A study of Homo sapiens with 6 samples.

How the data were processed

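Primary human preadipocytes, the fibroblast-like precursors of fat cells, came from subcutaneous adipose tissue and were sequenced undifferentiated (day 0, 3 libraries) and after culture in differentiation and maintenance media (day 14, 3 libraries). The libraries were made with QuantSeq FWD, a kit that reads the 3′ end of polyadenylated transcripts, so that a read marks a transcript rather than its length. Group and replicate number were taken from the sample titles. The labels do not say whether the replicates came from separate donors or cultures. The authors' p-values therefore measure the spread between these libraries. In how many libraries a gene moved in a given direction is not known.

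Per the submitters' processing notes, the tools used before deposit were cutadapt 2.8, Trim Galore 0.6.10, STAR 2.6.1d, Bowtie2, featureCounts 1.6.3 and DESeq2 1.40.2, with the genome build hg38; the gene annotation and the strand setting of the counting are not given in the sources used here. Each of the 3 deposited tables holds the authors' own comparison and no value per library. Per the file headers, the expression table gives for each of 26485 genes a mean over all libraries, which is a signal in normalised reads, a log2 fold change with its standard error, a p-value and an adjusted p-value. Per the file headers, the 2 polyadenylation tables (made with DEXSeq, by the names the authors gave the sheets) give per gene a score named RED, an adjusted p-value and a call of lengthened, shortened or no change. The score is taken here as the difference between day 14 and day 0 in the use of the distal against the proximal site, or of sites in the last exon against sites in introns; its log base is not stated in the deposited tables, so it is printed in the authors' units. The table for 3′ untranslated regions (UTRs) also gives the positions of both sites.

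The header of the expression table does not state the direction of the fold. It was read as day 14 over day 0, because the sheet names of the polyadenylation tables put differentiated before undifferentiated cells and because adipocyte genes such as ADIPOQ are positive. Of the listed genes, 7912 had a mean of 0 and 18547 had a p. The deposited adjusted p covers 16083 genes with a mean of at least 1.42, and a Benjamini-Hochberg adjustment recomputed over those genes differed from it by at most 1.39e-15. Among the 1996 genes with a mean above 0 and under 1, the deposited absolute log2 fold had a median of 0.157. Its standard error had a median of 1.02, so most folds of genes under that mean lie near 0. In 99.0% of genes the fold divided by its standard error lay below the z value of the deposited p. The median ratio of these values was 0.939. The deposited p therefore cannot be recovered from the fold and its standard error, and the cause was not tested.

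No total per library is part of the tables. The lowest means are whole sums of 6 values, each the worth of 1 read of 1 library in the mean; they account for 100% of the 1142 genes with a mean under 4 of the smallest steps, within 5e-06. In units of a size factor, by which reads are divided, the 3 steps seen in genes with negative folds corresponded to 1.05, 1.14 and 1.35, and the 3 in genes with positive folds to 0.779, 0.858 and 0.978. The day 0 libraries therefore had a mean size factor 1.36 times that of the day 14 libraries. The 10 highest genes held 6.24% of the sum of the means. A group mean was derived from the deposited mean and fitted fold. It is approximate where that fold differs from the ratio of the group means. A group was treated as at the floor where its derived mean lay under the worth of 3 reads over the group. That worth was taken in the group's library with the smallest size factor (0.949 at day 0, 1.28 at day 14). The fold of such a gene is given against that floor and is called a lower bound. It is a bound only if the true level of the lower group lay under the floor. Counting error is not covered in full where that group held some reads. Reads without molecular identifiers are also not independent molecules.

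The planned test of expression was limma on values per library. As the tables hold none, the authors' adjusted p at 0.05 was used, and the planned minimum mean of 10 became an alternative. Gene symbols were brought to current ones through RefSeq (assembly GRCh38.p14), in which 23758 of the expression symbols were current, 1514 were older symbols and 1213 were not matched. The 34 gene lists and the rules for named genes were fixed before the data were examined. Lists with at least 5 tested members were compared with all other genes by the cameraPR function of limma 3.58.1 in R 4.3.3, on the z value of the deposited p signed by the fold, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 33 lists. A correlation between genes could not be estimated without values per library, so presets of 0.05 and 0.1 were run as well. The same function was run on the RED of each polyadenylation table; the list tests of polyadenylation were not part of the plan made before the data were examined. Long non-coding RNA genes were taken from the RefSeq gene types. Shares were compared with Fisher's exact test and splits with the exact binomial test, all two-sided. Correlations across genes used 100000 permutations, whose smallest p is 1e-05. These tests and the exact intervals count genes as independent, which they are not, and do not measure the spread between libraries. Site positions were annotated with GENCODE release 29 on the same assembly: 72.9% of distal and 37.0% of proximal sites lay within 24 nt of an annotated transcript end on the same strand. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

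The text names the 8 rising and 8 falling genes with the largest fitted fold among those that passed with a derived mean of at least 100 in the higher group, the same for 4 and 4 long non-coding RNA genes with a mean of at least 50, and up to 3 members per list with the largest fold. From each polyadenylation table it names the 6 genes per direction with the smallest adjusted p and up to 6 list members. Some members that the rule would name are not reported here. Any tested transcription factor or polyadenylation factor of the lists may be named. The planned condition that all libraries of a group lie above the other's could not be applied. XIST, TSIX and genes of the Y chromosome were left out of named genes and plots. On simulated data, the worth of 1 read was recovered for every library in 20 of 20 tables of 18573 genes. In 100 shuffles of the 16083 z values the list test called 10 of 3300 lists, and it called 86.4% of lists shifted by 1 SD. Shuffling removes any correlation between genes, so these rates do not hold for lists whose members move together. The alternatives were other filters, thresholds, list statistics and preset correlations, and strata of mean expression.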

Results

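Differentiation of subcutaneous human preadipocytes into adipocytes was followed by 3′ end sequencing of 3 libraries at day 0 and 3 at day 14. The study asked how gene expression, long non-coding RNAs and the choice of polyadenylation site change in white adipogenesis. The values are the authors' comparisons of these groups, so each gene has a fold with a standard error (SE) but no value per library. In 99.0% of genes the fold divided by this SE lay below the z value of the p. A printed SE therefore cannot be used to check a printed p. Expression covers 18573 genes with reads, and usage of polyadenylation sites is given for 4211 genes in the 3′ UTR (untranslated region) and 8449 genes in introns. No total per library is given. By the worth of 1 read, size factors were 1.05 to 1.35 at day 0 against 0.779 to 0.978 at day 14. A size factor scales the reads and is not a read total, so depth was not measured.

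Adipocyte genes that were near 0 reads at day 0 rose, and mitotic genes fell to near 0. In the authors' deposited table, ADIPOQ, the adipokine adiponectin (chromosome 3, 186842710 to 186858463, hg38), was at least 68250.4-fold higher at day 14, with an adjusted p of 8.14e-50. PCK1, an enzyme of glyceroneogenesis, was at least 31477-fold higher in the authors' deposited table, and PPP1R1A, a protein phosphatase inhibitor, at least 13649-fold. The other rising genes with the largest fitted fold in the authors' deposited table were LGALS12 (at least 5552-fold), the glycerol channel AQP7 (4162-fold), the lipogenic transcription factor MLXIPL (3475-fold), the lipid droplet protein PLIN5 (1803-fold) and the glycerol-3-phosphate dehydrogenase GPD1, whose log2 fold was 14.79 (SE 1.39). Ranking by the lower bounds would give another order, in which PLIN4 lies above LGALS12. The gene with the largest fitted fall was the mitotic kinase AURKB (chromosome 17, 8204731 to 8210575), at least 1627-fold lower at day 14 in the authors' deposited table with an adjusted p of 2.91e-25.

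Of the other genes with the largest fitted falls, DLGAP5, NEK2, SPC25 and CIT act in mitosis and cytokinesis and UHRF1 in the copying of DNA methylation. The authors' deposited table put DLGAP5 at least 671-fold lower, SPC25 376-fold, CIT 349-fold, NEK2 339-fold and UHRF1 174-fold. LRRC15 and CDCP1, both membrane proteins, were at least 373-fold and 191-fold lower in the authors' deposited table. In all, 6175 of 16083 tested genes passed an adjusted p of 0.05 in the authors' deposited table, 3093 higher and 3082 lower at day 14; 2251 and 2234 of these had an absolute log2 fold of at least 1. In 419 of the called genes, 175 higher and 244 lower, the lower group was at or under the floor. Their folds are given as lower bounds against that floor.

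**Figure D1:**
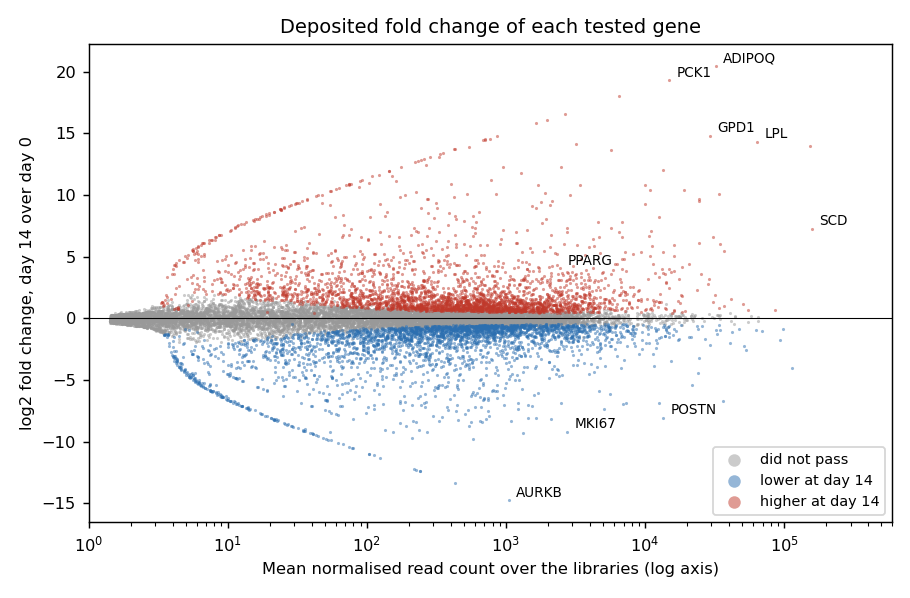
Deposited log2 fold change (day 14 over day 0) against the mean normalised read count over all libraries (log axis), 1 point per tested gene, coloured by direction where the authors' adjusted p was under 0.05. The 3093 higher and 3082 lower genes lie on both sides of 0; the curved outer edges hold genes near 0 reads in a group, whose plotted folds are fitted values and not measured ratios.

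Genes for taking up, making and storing fat rose together. Of 23 tested genes of fatty acid uptake and triglyceride synthesis, 18 rose and 1 fell, with LPL, the lipoprotein lipase, at a log2 fold of 14.33 (SE 1.17) in the authors' deposited table. In de novo lipogenesis 18 of 19 rose and none fell. There, the authors' deposited table gave log2 folds of 9.52 (SE 0.28) for the acetyl-CoA carboxylase ACACB and 7.27 (SE 0.43) for the desaturase SCD, and 10.84 (SE 1.30) for THRSP. Of 17 lipid droplet proteins 12 rose and 3 fell, and PLIN4 was at least 6746-fold higher in the authors' deposited table. In lipolysis 15 of 19 genes rose and none fell, led by PDE3B (10.81, SE 0.52) and the hormone-sensitive lipase LIPE (9.67, SE 0.27) in the authors' deposited table. The list test (limma cameraPR) gave adjusted p of 3.76e-21, 2.89e-28, 8.45e-09 and 4.59e-26 for these lists in that order.

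Insulin-responsive and secreted adipocyte genes followed the same direction. Of 18 genes of insulin signalling and glucose uptake, 15 rose and 1 fell, and the glucose transporter SLC2A4 had a log2 fold of 10.10 (SE 0.89) in the authors' deposited table. Of 17 secreted adipokines 11 rose and 3 fell; APOE and RBP4 had log2 folds of 10.08 (SE 0.29) and 9.24 (SE 0.30) in the authors' deposited table. Among 18 glucocorticoid response genes 11 rose and 1 fell, including PDK4 (7.12, SE 0.23), MAOA (7.01, SE 0.35) and SERPINA3 (5.06, SE 0.62) in the authors' deposited table. Of 18 thermogenic adipocyte markers 11 rose and 2 fell. UCP1, the uncoupling protein of brown fat, chosen for naming after its values were seen, is listed at 0. CIDEA and CKMT1A, in contrast, were at least 702-fold and 538-fold higher in the authors' deposited table. CKMT1A has a near-identical copy, CKMT1B, and how reads were assigned between the copies is not given. The list test (limma cameraPR) gave adjusted p of 2.87e-13, 5.9e-19, 2.02e-13 and 9.79e-10. Some genes are in more than 1 list, such as PDK4, ZBTB16 and PPARGC1A, so the list tests are not independent. Cells at day 14 had been cultured in differentiation and maintenance media. A response to these media cannot be told apart from differentiation.

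Mitochondrial and sterol pathways rose in nearly every member. All 22 cholesterol synthesis genes rose, and MVD and INSIG1 had log2 folds of 4.07 (SE 0.86) and 3.64 (SE 0.36) in the authors' deposited table. In fatty acid oxidation 21 of 24 rose and 1 fell, with log2 folds of 6.07 (SE 0.46) for PPARGC1A, a coactivator of mitochondrial genes, and 4.80 (SE 0.25) for ACADS in the authors' deposited table. The nuclear-encoded respiratory chain rose in 43 of 46 subunits with none falling, by a smaller median log2 fold of 1.16; NDUFB5 led at 2.15 (SE 0.22) in the authors' deposited table. In the citric acid cycle 19 of 21 rose and none fell, with PC, pyruvate carboxylase, at 4.26 (SE 0.44) in the authors' deposited table, and in branched-chain amino acid catabolism 18 of 20 rose and none fell, with ALDH6A1 at 3.54 (SE 0.27). Adjusted p of the list test (limma cameraPR) were 3.62e-13, 5.05e-21, 7.45e-14, 1.23e-08 and 1.3e-10.

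Among 21 adipogenic transcription factors, 15 rose, 3 fell and 3 did not pass (limma cameraPR, adjusted p = 1.36e-11). PPARG, the master regulator of adipogenesis, had a log2 fold of 4.08 (SE 0.32) and CEBPA one of 7.33 (SE 0.96) in the authors' deposited table. KLF15 (7.16, SE 0.34), NR1H3 (6.14, SE 0.44), ZBTB16 (4.35, SE 0.35), FOXO1 (4.30, SE 0.25) and STAT5A (4.14, SE 0.26) also rose in the authors' deposited table. The early factor CEBPB rose by 0.83 (SE 0.20), while KLF4 (-1.46, SE 0.35), EBF2 (-1.27, SE 0.37) and the glucocorticoid receptor NR3C1 (-0.58, SE 0.19) fell in the authors' deposited table. CEBPD (0.59), KLF5 (-0.18) and TLE3 (-0.84) did not pass, with adjusted p of 0.0975, 0.776 and 0.0824 in the authors' deposited table.

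Tested genes of the cell cycle list fell without exception. All 30 tested cell cycle genes fell, with a median log2 fold of -5.10 (limma cameraPR, adjusted p = 1.74e-38); MKI67, a marker of cycling cells, had -9.18 (SE 1.14) in the authors' deposited table and BUB1 was at least 417-fold lower. Extracellular matrix and cytoskeletal genes fell as well. Of 28 collagens and matrix genes 20 fell and none rose, with POSTN at -8.06 (SE 1.21), TGFBI at -6.70 (SE 0.37) and BGN at -4.48 (SE 0.81) in the authors' deposited table. In the YAP and TGF-beta response 15 of 20 fell and 2 rose, with INHBA at -4.60 (SE 0.78) in the authors' deposited table. Of 22 contractile cytoskeleton genes 14 fell and none rose, led by TPM1 (-3.83, SE 0.30) and ACTG1 (-2.25, SE 0.27) in the authors' deposited table. The list test (limma cameraPR) gave adjusted p of 1.15e-08, 1.99e-07 and 6.24e-06 for these 3 lists.

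Basement membrane genes went the other way from the interstitial matrix. COL4A1 and COL4A2, which form type IV collagen, had log2 folds of 3.20 (SE 0.34) and 3.22 (SE 0.25), and NID1 had 2.47 (SE 0.33), in the authors' deposited table. Of the 13 members 6 rose and 1 fell (limma cameraPR, adjusted p = 0.00541), and the call was lost at a preset correlation of 0.1 (adjusted p = 0.0606).

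Signalling and RNA-processing lists fell less uniformly. In the Wnt and Notch list 11 of 24 fell and 3 rose, with WNT5B at -3.65 (SE 0.26), DKK3 at -3.39 (SE 0.39) and WNT2 at least 45.0-fold lower in the authors' deposited table. Of 36 splicing regulators 19 fell and 3 rose; HNRNPA1 had -1.50 (SE 0.22), and the 3 that rose in the authors' deposited table were NOVA1 (2.67, SE 0.34), CELF2 (1.79, SE 0.23) and QKI (1.24, SE 0.24). The list test (limma cameraPR) gave adjusted p of 0.0379 and 0.00697, and at a preset correlation of 0.05 neither passed (adjusted p of 0.138 and 0.0741).

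Lists that did not pass as a whole still held changed members. Of 23 preadipocyte and stromal progenitor markers 9 fell and 4 rose (limma cameraPR, adjusted p = 0.133): PI16 had -6.11 (SE 1.15), while CD34 (4.68, SE 0.73) and GATA3 (4.91, SE 1.09) rose in the authors' deposited table. Among 22 inflammatory and NF-kB genes 4 rose and 6 fell (adjusted p = 0.755, limma cameraPR), with complement C3 at 4.52 (SE 0.35), CXCL2 at -4.16 (SE 1.04) and CXCL8 at least 122-fold lower in the authors' deposited table. Of 20 stress genes 4 rose and 6 fell (limma cameraPR, adjusted p = 0.342), including the chaperones HSPA5 (-1.76, SE 0.37) and HSP90B1 (-1.47, SE 0.27) and HMOX1 (-2.47, SE 0.27) in the authors' deposited table. Of 28 cleavage and polyadenylation factors 2 rose, 6 fell and 20 did not pass (limma cameraPR, adjusted p = 0.295). The 6 that fell, FIP1L1, SNRPA, RBBP6, CSTF3, U2AF2 and CDK12, had log2 folds of -0.69, -0.65, -0.63, -0.60, -0.60 and -0.51 in the authors' deposited table, and CSTF2T (0.84) and SSU72 (0.61) rose.

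Markers of other cell types were measured beside these. Of 10 endothelial markers 3 fell and none rose, of 7 macrophage and leukocyte markers 2 rose and 2 fell, and of 10 mural cell markers 1 rose and 1 fell. Mesothelial markers had 1 rise and 3 falls among 6, and osteoblast and chondrocyte markers 1 and 3 among 9. None of these lists passed the list test (limma cameraPR, adjusted p of 0.342, 0.977, 0.977, 0.606 and 0.148). Single members moved far: CD14, a monocyte marker, had a log2 fold of 4.72 (SE 0.45), MCAM 6.44 (SE 0.79) and CALB2 5.93 (SE 0.87) in the authors' deposited table, while the endothelial receptor TEK was at least 114-fold and the bone matrix protein SPP1 at least 55.3-fold lower.

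Cytosolic ribosomal proteins were nearly level, with 1 of 34 rising, 1 falling and a median log2 fold of 0.11 (limma cameraPR, adjusted p = 0.67). Among 14 reference genes 2 rose and 4 fell (limma cameraPR, adjusted p = 0.67). ACTB had -1.65 (SE 0.25), GAPDH -1.23 (SE 0.24) and SDHA 1.27 (SE 0.21) in the authors' deposited table. The median of the reference genes was 0.04, while their mean log2 fold was -0.16 and the test pointed down. The mitochondrially encoded transcripts had no tested member.

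Counts adjusted over the list alone equalled those above for 19 of the 33 lists. For the other 14, adjusted over the list alone, the numbers that rose and fell were 16 and 4 (transcription factors), 19 and 1 (uptake and triglycerides), 12 and 3 (adipokines), 21 and 0 (citric acid cycle), 45 and 0 (respiratory chain) and 19 and 0 (branched-chain amino acids). They were 1 and 21 for the matrix, 1 and 15 for the cytoskeleton, 3 and 12 for Wnt and Notch, 6 and 8 for inflammation, 2 and 3 for polyadenylation factors, 3 and 22 for splicing, 1 and 0 for ribosomal proteins and 4 and 7 for stress, each adjusted over the list alone.

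**Figure D2:**
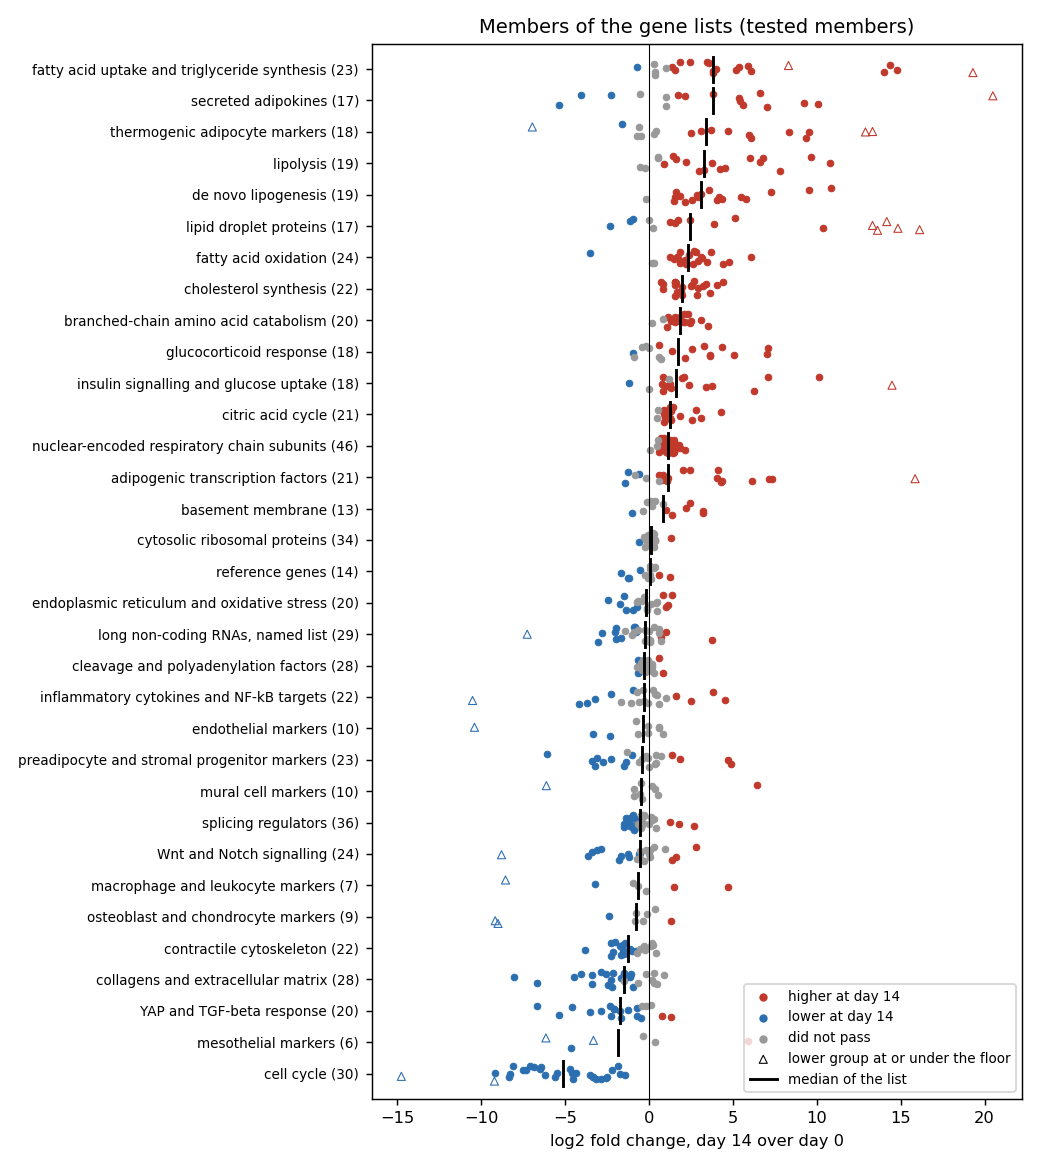
Deposited log2 fold change (day 14 over day 0) of each tested member of the 33 gene lists, ordered by list median (black bar), with the number of tested members in brackets. Points are coloured by the authors' adjusted p at 0.05, and triangles mark members whose lower group was at or under the floor; all 30 cell cycle genes lie below 0 and all 22 cholesterol synthesis genes above it.

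Long non-coding RNA genes that passed mostly rose. Of 1097 tested, 291 passed, 201 higher and 90 lower at day 14 (exact binomial p = 6.69e-11). The 5676 called protein-coding genes, in contrast, split into 2768 and 2908. Genes are not independent replicates, so the binomial p does not measure the spread between libraries. In the authors' deposited table PRKAG2-AS1 was at least 888-fold higher, RHOXF1-AS1 255-fold, ADIPOQ-AS1 156-fold and ALDH1L1-AS2 89.5-fold. ADIPOQ-AS1 overlaps ADIPOQ on chromosome 3, and since the strand setting of the counting is not given, reads of the overlapping gene cannot be excluded for it or for the other antisense genes. With a derived mean of at least 50 in the higher group, 4 genes had the largest fitted falls in the authors' deposited table. They were LINC01050 (at least 121-fold), APCDD1L-DT (77.5-fold), LINC01204 (62.5-fold) and LINC00673 (53.1-fold), all given as lower bounds. Of 29 tested members of the fixed list of named long non-coding RNAs, 3 rose and 10 fell (limma cameraPR, adjusted p = 0.219); CEBPA-DT, which is divergent to CEBPA, had a log2 fold of 3.74 (SE 0.73) and MIR31HG one of -3.03 (SE 0.62) in the authors' deposited table.

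The share called was 26.5% of long non-coding RNA genes against 40.7% of 13929 protein-coding genes, an odds ratio of 0.525 (Fisher's exact test, two-sided, p = 2.61e-21). That order depended on mean expression. The median of the mean normalised reads was 11.8 against 280.3. Among genes with a mean of at least 50 the shares were 60.0% of 250 against 48.7% of 10448 (odds ratio 1.58, Fisher's exact p = 0.000415).

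**Figure D3:**
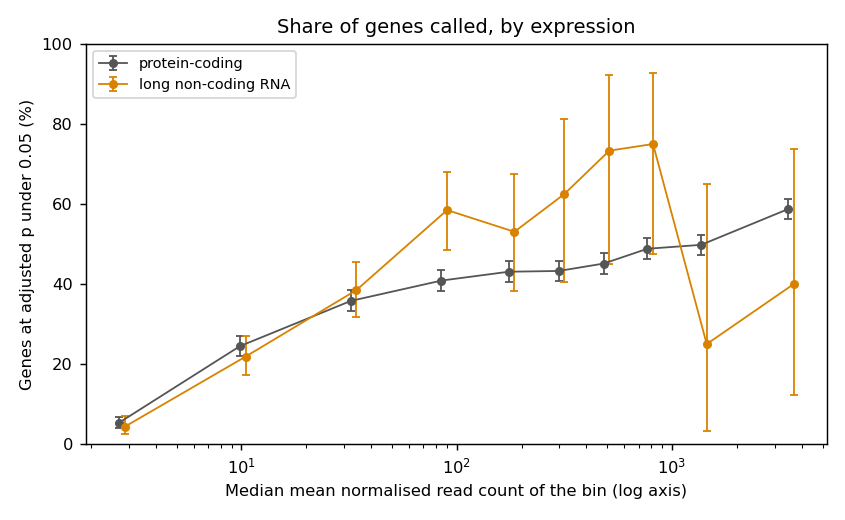
Percent of genes with an authors' adjusted p under 0.05 in 10 bins of mean normalised reads (log axis), for protein-coding and long non-coding RNA genes, with exact 95% binomial intervals. Long non-coding RNA genes lie below protein-coding genes in bins 1, 2, 9 and 10 (4.36% against 5.37% in bin 1) and above them in bins 3 to 8 (58.5% against 40.9% in bin 4); bins 9 and 10 hold 8 and 10 of them.

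Polyadenylation site choice in the 3′ UTR shifted in both directions. Lengthening means more use of the distal site at day 14. In the authors' deposited table the lengthened genes with the smallest adjusted p were PHLDA1 (RED 7.98), the potassium channel KCNK3 (3.62), PCLAF (4.43), CCNQ (3.57), SPTSSA (1.86) and NDRG2 (4.82). Shortened genes were led by the matrix protein SPARC (RED -2.37), GLCE (-5.54), the splicing regulator QKI (-2.76), HSPBP1 (-3.41), SCD (-2.19) and SHCBP1 (-4.11) in the authors' deposited table. Adjusted p ran from 1.1e-26 for PHLDA1 to 8.6e-09 for NDRG2 and from 4.42e-21 for SPARC to 2.52e-13 for SHCBP1 in the authors' deposited table. NUDT21, a subunit of cleavage factor I, was itself shortened (RED -1.20, adjusted p = 0.000705), and E2F1 was lengthened (RED 2.10, adjusted p = 3.93e-05) in the authors' deposited table.

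Both sites of each of these 14 genes lie in an annotated 3′ UTR exon. In PHLDA1, KCNK3, SPTSSA, SPARC and SHCBP1, however, neither site lay within 24 nt of an annotated transcript end. In each of the others the proximal or the distal site did. The proximal and distal sites of PHLDA1 lay 4122 and 2573 nt from such an end, and those of SPARC 45 and 354 nt. Whether the unannotated positions are true polyadenylation sites was not tested. In hg38 the authors' deposited table places the proximal and distal sites of PHLDA1 at 76029569 and 76028020 on the minus strand of chromosome 12, those of SPARC at 151662443 and 151661450 on the minus strand of chromosome 5, and those of SCD at 100363619 and 100364825 on the plus strand of chromosome 10. The alternative segment of QKI (chromosome 6, 163571719 to 163573795) spans 2076 nt and that of NUDT21 (chromosome 16, 56429137 to 56432625) 3488 nt, against 140 nt in KCNK3, by the positions in the authors' deposited table.

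In all, 148 of 4211 genes passed, 78 lengthened and 70 shortened, a split that did not differ from even (exact binomial test, two-sided, p = 0.565), with a median RED of 0.033 over all genes. The distance between sites had a median of 741 nt in the table, 1078 nt in lengthened and 973.5 nt in shortened genes. None of the 19 gene lists with at least 5 members in the table was enriched among lengthened or shortened genes (Fisher's exact test, lowest adjusted p 0.526). The largest list held 20 genes and only 148 of 4211 genes were called. This test could therefore hardly call a list, and no conclusion is drawn from it.

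**Figure D4:**
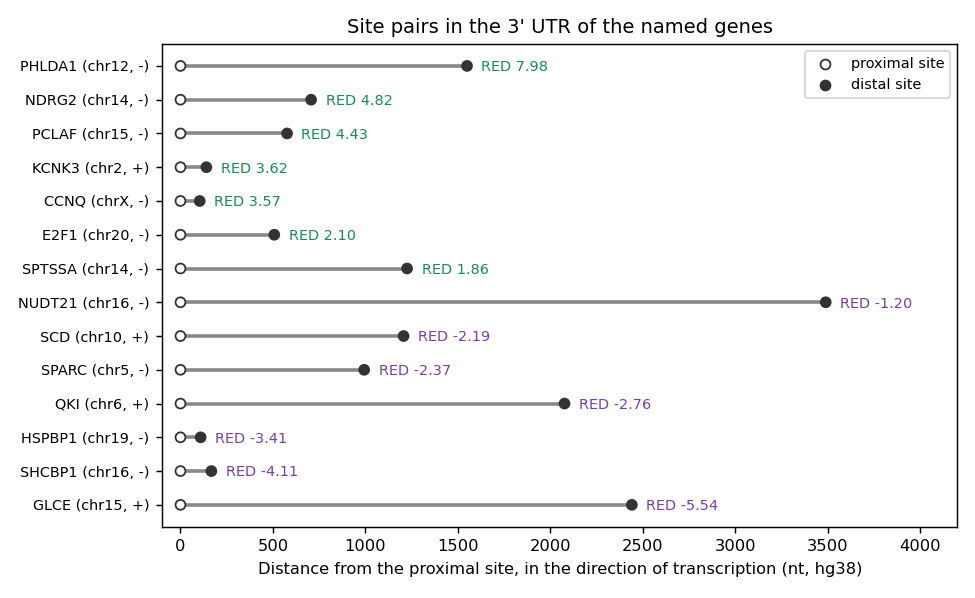
Proximal (open) and distal (filled) polyadenylation sites of the 14 named genes, drawn to scale as distance in nt from the proximal site in the direction of transcription (hg38), with the authors' RED score beside each. Distances range from 104 nt in CCNQ to 3488 nt in NUDT21, and long and short segments occur among both lengthened and shortened genes.

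Intronic sites changed in more genes, and mostly towards lengthening, that is, less use of intronic sites at day 14. Ranked by adjusted p and not by score, ACACB (RED 6.94) led the lengthened genes in the authors' deposited table. NRCAM (5.69), MLYCD (4.39), AOX1, the growth hormone receptor GHR (5.85) and APCDD1 (4.59) followed. Shortened genes with the smallest adjusted p were MLKL (RED -5.52), BLMH (-3.11), PRR11 (-4.91), KIF4A (-5.50), HNRNPH1 (-3.16) and PRC1 (-4.77) in the authors' deposited table. PRR11, KIF4A and PRC1 act in mitosis. List members with the smallest adjusted p also included ACADS (4.34), PIK3R1, LPIN1 (2.23) and APOC1 (6.55), all lengthened in the authors' deposited table. Of 8449 genes 1257 passed, 816 lengthened and 441 shortened (exact binomial test, two-sided, p = 2.2e-26). Over all 8449 genes the median RED was 0.175 and 56.8% had a RED above 0. The test against an even split therefore partly reflects a shift of the whole table. Positions of intronic sites were not used here.

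Several metabolic lists, but not all, were enriched among lengthened genes and the cell cycle among shortened ones. Of 21 fatty acid oxidation genes 12 were lengthened and none shortened (Fisher's exact test, adjusted p = 2.1e-06 over 27 lists). Insulin signalling had 7 of 10 lengthened, de novo lipogenesis 8 of 18, branched-chain amino acid catabolism 8 of 17, the citric acid cycle 6 of 15 and the glucocorticoid response 5 of 10 (Fisher's exact test, adjusted p of 9.5e-05, 0.00089, 0.00072, 0.0084 and 0.0075). Fatty acid uptake (5 of 13), transcription factors (5 of 15) and lipolysis (4 of 10) also passed, with adjusted p of 0.0213, 0.0338 and 0.0338 by Fisher's exact test. Cholesterol synthesis (1 of 18 lengthened), the respiratory chain (3 of 30) and lipid droplet proteins (2 of 10, with 3 shortened) did not pass by this count. Of 15 cell cycle genes 9 were shortened and none lengthened (Fisher's exact test, adjusted p = 2.7e-07). A list test on the RED of all members (limma cameraPR) differed for 5 lists. It did not call insulin signalling, the citric acid cycle or the glucocorticoid response (adjusted p of 0.0965, 0.142 and 0.119, limma cameraPR), and it called cholesterol synthesis and the respiratory chain higher (adjusted p of 0.0163 and 0.0303, limma cameraPR). On ranks lipolysis did not pass either (limma cameraPR, adjusted p = 0.0567). Once the linear trend of RED on the expression fold was removed, the cell cycle passed (limma cameraPR, adjusted p = 0.0174) and none of the metabolic lists or the transcription factors did. None of the 25 cleavage and polyadenylation factors in the table was called.

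The direction of intronic usage followed the direction of expression. Of 811 lengthened genes with tested expression, 531 rose and 30 fell; of 433 shortened genes, 20 rose and 291 fell (odds ratio 257.5, Fisher's exact p = 1.94e-167). ACACB, lengthened, had a log2 fold of expression of 9.52, and KIF4A and PRR11, shortened, had -7.16 and -6.83 in the authors' deposited table. Genes called for intronic usage were more often called for expression, 70.1% against 37.9% (odds ratio 3.84, Fisher's exact p = 4.15e-99). Across 8298 genes, which are not independent replicates, RED and the expression fold had a Spearman rho of 0.53 (permutation p = 1e-05, the smallest the permutations can give). As RED is taken here, reads of the last exon enter both RED and the expression fold. A positive relation is therefore partly built in, and these p-values do not test whether site usage was regulated.

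In the 3′ UTR the relation was slight. Of genes called for 3′ UTR usage 53.4% were called for expression, against 42.6% of the others (odds ratio 1.54, Fisher's exact p = 0.0106), and among the 1385 genes of middle and the 1385 of highest mean expression the odds ratios were 1.05 and 1.18, with 95% intervals that include 1 (0.547 to 2.03 and 0.755 to 1.84). Among the 1385 of lowest mean expression it was 2.73 (Fisher's exact p = 0.0158). Across 4155 genes rho was 0.05 (permutation p = 0.0003). Directions did not track expression among the 78 genes called in both (odds ratio 1.44, Fisher's exact p = 0.494): SCD was shortened with a log2 fold of 7.27 and SHCBP1 with one of -8.18 in the authors' deposited table, while KCNK3 (9.52) and PCLAF (-7.05) were both lengthened. Of the 3602 genes in both polyadenylation tables, 24 were called in both against 18.0 expected (Fisher's exact p = 0.120), and the RED values had a rho of 0.03 (permutation p = 0.118).

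**Figure D5:**
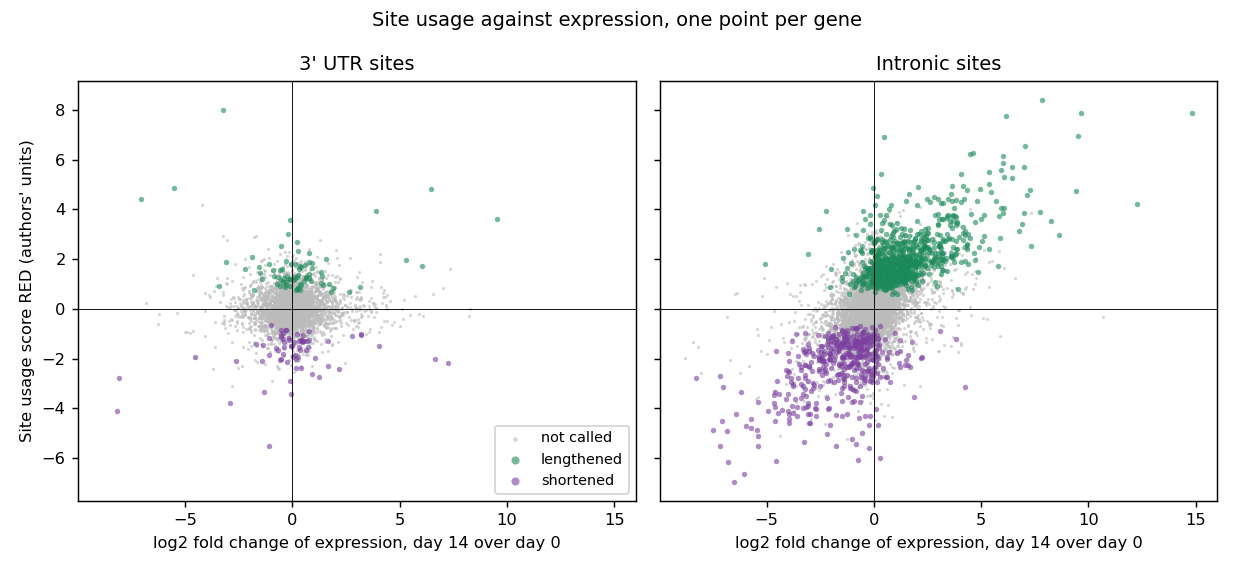
The authors' RED score against the log2 fold change of expression (day 14 over day 0), 1 point per gene, for 3′ UTR sites (left, 4155 genes) and intronic sites (right, 8298 genes), coloured by the authors' call. Intronic points run along the rising diagonal (rho 0.53) and 3′ UTR points do not (rho 0.05).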

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

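The authors' deposited table gives 14 genes a mean and a fold but no p, leaving out genes excluded from naming. The expression comparison here therefore did not use them. They are named, after their values were seen, because they carry reads but no p for expression. By mean, the highest in the authors' deposited table were AKR1B1 (9623 normalised reads), MTRNR2L8 (1600.3), STMN2 (457), TMEM176B (433) and the metallothionein MT1A (431). TMEM176B and TMEM176A had log2 folds of 5.16 (SE 1.24) and 5.83 (SE 1.29) and AKR1B1 one of 2.35 (SE 1.37) in the authors' deposited table. CDKN2A, which encodes an inhibitor of the cell cycle, had 0.41 (SE 0.78) in the authors' deposited table. MTRNR2L8 resembles mitochondrial RNA, so its reads are uncertain. No explanation was tested. Without values per library it cannot be told whether any of these folds rests on a single library.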

How the results depend on the processing

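The use of the planned minimum mean of 10 as an alternative to the authors' filter, correlations of 0.05 and 0.1, ranks, the fold as list statistic, a minimum fold and the binned odds ratio were chosen after seeing the data. The count of changed genes lay between 4485 and 6052 under the alternatives, within 1.5 times of 6175, with 50.2% to 51.1% higher. Of 33 lists 21 were called; alternatives called 18 to 21, and no list was called in opposite directions; splicing regulators (adjusted p of 0.000201 to 0.266 over the alternatives, limma cameraPR), Wnt and Notch signalling (0.0303 to 0.265) and the basement membrane (0.0114 to 0.121) lost the call under some, and with the fold as statistic endothelial and osteoblast markers gained one. Long non-coding RNA calls fell to 150 at a mean of at least 50, where fewer genes were tested. The odds ratio of their share against protein-coding genes was 0.906 at a mean of at least 10 (Fisher's exact p = 0.252). It turned above 1 at a mean of at least 50 (1.58) and within 10 bins of mean expression (1.19, without an interval). The order of the shares therefore depended on mean expression. In bins 1 and 2, of lowest mean, the share was still lower (4.36% against 5.37% and 21.9% against 24.5%). It was also lower in bins 9 and 10, and higher in bins 3 to 8. Stricter and looser thresholds gave 87 and 230 genes for the 3′ UTR (adjusted p 0.01 and 0.1) and 758 for introns at 0.01; the intronic majority of lengthened genes held under each, at 63.5% to 65.3%. The 3′ UTR overlap with expression had odds ratios of 1.05 and 1.18 in the genes of middle and highest mean expression; the cause was not tested.

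No paired analysis was possible because the tables give no value per library. For the same reason other pseudocounts, rescaling, quantile normalisation, robust limma, leaving out libraries, count models, fry, an estimated correlation and other splits of the samples were not run; counting genes in place of features changes nothing, as each gene has 1 feature. Genes with few reads limit all counts.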

Other observations

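The symbol families, the test of the trend in RED, and the 3 tests of technical explanations for intronic usage were chosen after seeing the data. Among 110 families of genes that share the letters before the number in their symbol, each with at least 15 tested members, 6 passed the list test (limma cameraPR) both on z values and on ranks. Kinesins (KIF), motors of which many serve the spindle, fell in 19 of 33 and rose in 1 (adjusted p = 1.2e-08). KIF14 and KIF18B had log2 folds of -8.28 (SE 0.61) and -8.35 (SE 0.88) in the authors' deposited table. Centrosomal proteins (CEP) fell in 25 of 40 and rose in 3 (limma cameraPR, adjusted p = 0.00037), with CEP55 at -9.34 (SE 0.55) in the authors' deposited table. Nucleoporins (NUP), which build the nuclear pore, fell in 11 of 22 and rose in none (limma cameraPR, adjusted p = 0.0388), by smaller folds, such as -1.47 (SE 0.29) for NUP62 and -1.37 (SE 0.28) for NUP93 in the authors' deposited table.

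Aldehyde dehydrogenases (ALDH) rose in 12 of 19 and fell in 2 (limma cameraPR, adjusted p = 0.00037; the family as formed also holds the antisense gene ALDH1L1-AS2). ALDH1L1 was at least 599-fold higher and ALDH5A1 had a log2 fold of 3.80 (SE 0.50) in the authors' deposited table. The COX family rose in 16 of 23 with none falling (limma cameraPR, adjusted p = 4.1e-05), but 10 of its members are also in a fixed list; COX7A1 led at 2.51 (SE 0.27) in the authors' deposited table. The CDC family fell in 12 of 31 and rose in 3 (limma cameraPR, adjusted p = 0.0388).

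Intronic usage followed the expression fold, and 3 technical explanations were weighed. None of the tests removes the reads of the last exon that RED and the expression fold share. Counting noise of genes with few reads in all is argued against, since rho was 0.528 among genes with a mean of at least 2000. That mean covers the whole gene and no count per intronic site is given. Noise from few reads at intronic sites is therefore not decided. Easier calls with more reads are argued against as well, since the odds ratio of both calls was at least 3.36 in the genes of lowest, middle and highest mean expression. Intronic reads that stay at a constant level while the spliced transcript changes, for instance from unspliced RNA or priming inside introns, would give RED the sign of the fold in nearly every strongly changed gene. It had that sign in 88.9% of 434 genes (exact 95% interval 85.6 to 91.7). That share lies below the level set to argue against the explanation, but the interval includes that level. The interval lies wholly below the 95% of genes that the explanation was set to require. Both levels were set after the data were seen. This explanation and a regulated shift to the last exon therefore cannot be told apart without reads per site.

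Once its linear trend on the expression fold was removed, the intronic score set 2 lists apart. Cell cycle genes were lower before (limma cameraPR, adjusted p = 2.9e-15) and after that step (limma cameraPR, adjusted p = 0.0174). Collagens and matrix genes, whose expression fell, pointed lower before it without passing (limma cameraPR, adjusted p = 0.678) and were higher after it (limma cameraPR, adjusted p = 0.0174), so that call rests on the subtraction. Fatty acid oxidation, de novo lipogenesis and branched-chain amino acid catabolism passed before the step (adjusted p of 8.1e-07, 1.7e-06 and 0.0011, limma cameraPR) and not after it (0.691, 0.646 and 0.730). The same held for lipolysis, fatty acid uptake, transcription factors, cholesterol synthesis and the respiratory chain, with adjusted p of 0.959, 0.691, 0.917, 0.646 and 0.899 after it (limma cameraPR).

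Splicing regulators fell as a list, with a median log2 fold of -0.53. That median lay at percentile 0.14 of 10000 random lists matched on mean expression, whose central 95% ran from -0.33 to 0.41. High mean expression alone is therefore argued against. The genes of the random lists were drawn independently, so that range is too narrow if the members move together. A fall tied to the exit from the cell cycle is a candidate explanation that was not tested. The list's call depended on the preset correlation (limma cameraPR, adjusted p of 0.0741 at 0.05). It also depended on the statistic (limma cameraPR, adjusted p of 0.266 with the log2 fold).

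Called long non-coding RNA genes rose in 69.1% (exact 95% interval 63.4 to 74.3). Low expression is argued against, since called protein-coding genes of matched mean rose in 45.4%. Reads of a changed protein-coding neighbour are argued against as the whole cause, since 68.0% (117 of 172, exact 95% interval 60.5 to 74.9) rose among those with no called protein-coding gene within 10 kb. Neighbours still moved together: 91 of 119 long non-coding RNA genes with such a neighbour went its way, or that of most of them (76.5%, against 48.7% with directions shuffled, permutation p = 1e-05, the smallest the permutations can give), so shared reads or shared control may act at those loci, and a regulated rise of non-coding transcripts in adipocytes remains a hypothesis.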
